A study of Mus musculus with 2 samples.

How the data were processed

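Mammary gland RNA of Gata3 het and null mice was compared on 2 spotted oligonucleotide arrays of about 38000 features, per the labels. Total RNA was extracted with Trizol, het RNA was labelled with Cy5 and null RNA with Cy3, and the authors applied lowess normalization within print-tip groups in Acuity 4.0, per the series' design text. The deposited values are log ratios of the channels of each array and were read as log2 values. The log base, the direction of the ratio, any centring, the background correction and the spot filters are not given in the sources used here. The log2 reading rests on the range of the values and on the usual scale of that software. Another base would rescale every log2 value and fold. All 38976 features had a value on both arrays, and 0 columns of values were left unused. Spot intensities were not used here, so neither a filter on dim spots nor matching by signal was possible, and the number of arrays limits the precision.

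Of the features, 22973 had 1 gene symbol in the platform annotation, 0 had several and 16003 had none. All 22973 were matched by Entrez ID to the RefSeq gene table of assembly GRCm38.p6, which was used for names alone, and they stood for 15056 genes. No coordinates are given because the build behind the array design is not given in the sources used here.

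The ratios were tested against 0 with limma 3.58.1 in R 4.3.3, with an intercept alone and the default empirical Bayes prior, two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The 2 arrays leave 1 residual degree of freedom per feature, and the fitted prior added 5.32. An exact sign-flip test of 2 arrays cannot go below p = 0.5, so the test rests on the variance shared across features. Neither a dye term nor a pairing could be fitted, since both arrays had the same orientation and genotype was compared within each array. Features at least 2-fold from 0 on both arrays were counted beside 1000 seeded shuffles.

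Gene lists, 23 in all, were tested with limma's camera on gene-level ratios, the features of a gene being averaged, with a preset correlation of 0.01 and at least 5 measured genes. They held 480 genes, of which 403 were measured. The lists covered luminal hormone-sensing cells, luminal epithelium, alveolar and milk genes, basal myoepithelial cells, basement membrane, white and brown adipocytes, lipid synthesis, oxidative phosphorylation, fibroblasts, endothelium, macrophages, T cells, B cells, skeletal muscle, skin, erythroid cells, cell cycle, cell death, involution, interferon response, ribosomal proteins and the unfolded protein response. Single members of the lists were taken from the gene-level limma fit.

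The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Gata3 first, then 12 gene symbols in each direction. Features past the adjusted threshold with one sign on both arrays came first, by absolute mean. The remaining places went to features not past it, by the smaller absolute value of the arrays, and all 24 were of this second kind. From each list up to 4 members with one sign on both arrays and the largest absolute mean were named. Members that passed the gene-level test are all among these. Foxa1, Fabp4, Csn2, Lalba, the genes with 20 or more features and the olfactory receptors were named after their values were seen.

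Both procedures were tested on simulated data. With variances drawn from the fitted prior for 38976 features, 1 of 50 features with a simulated log2 ratio of 1 was called, 48 of 50 at 2, and 50 of 50 at 3 and at 4. Of the unchanged features 15 were called. With 15056 simulated genes, camera called 4 of 4 lists shifted by 0.5 and 1 of 19 unshifted lists, and the comparison with random lists, run there with 2000 draws in place of 10000, called 4 of 4 and 2 of 19. The lists called unshifted are those not picked for a shift. Lists share some genes, such as Glycam1 and Cidea, so some unshifted lists held a shifted member. Genes shared by shifted lists, such as Itga6, were shifted more than once. Apart from the planted shifts, simulated values were independent between arrays and between genes. The real arrays had a Pearson r of 0.616 over genes, so the simulations do not show error rates under such shared effects.

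Alternatives tried were median subtraction, scaling the arrays to equal median absolute deviation, quantile normalization, dropping features whose arrays differed by more than 1, a robust prior, tests of genes in place of features, an adjusted p of 0.1, limma's treat against 0.5, the turned sign, other fold minimums and other list tests. Leaving out sensory receptor genes, and scaling 48 equal runs of consecutive features alike, were added after seeing the data. Intervals in the closing section come from 2000 bootstrap draws over genes, or over features for the spread along the feature order. Figures were drawn with matplotlib 3.10.9.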

Results

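The mammary glands of adult mice with a doxycycline-inducible deletion of Gata3 were compared by two-colour arrays. Gata3 encodes a zinc finger transcription factor of the luminal epithelium. Both genotypes carried WAP-rtTA-Cre, which produces Cre recombinase in mammary epithelial cells when doxycycline is given, and both were treated for 5 days. Mice with 1 floxed and 1 wild-type Gata3 allele (het) were set against mice with both alleles floxed (null). There were 2 arrays, each carrying het RNA in Cy5 and null RNA in Cy3, and 0 arrays had the dyes exchanged. The labels do not say whether the arrays held RNA of separate animals, so the errors below measure the spread between these 2 arrays, which may be technical.

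Every one of the 38976 features had a log ratio on both arrays. The median was -0.00 on array 1 and -0.03 on array 2, and the SD across features was 0.67 and 0.44. The sources used here do not state which channel was the numerator. A positive ratio means more RNA in the het gland if Cy5 was divided by Cy3, and more in the null gland if Cy3 was divided by Cy5. Ratios are therefore described as positive or negative as deposited, and under the other reading every sign below is turned.

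Gata3 itself, the deleted gene, was measured by 1 feature. Its ratio was 1.60 on array 1 and 0.21 on array 2, a mean of 0.90 ± 0.98 (SD, n = 2). These ratios are 3.02-fold on array 1 and 1.15-fold on array 2. Among all features the Gata3 ratio stood at percentile 97.4 on array 1 and 71.9 on array 2. Gata3 did not pass the test over all features (limma, adjusted p = 0.188), with a 95% interval of the mean from 0.08 to 1.72. That interval uses limma's standard error of 0.34, which borrows from the spread of the other features. It excludes 0 only through this borrowing, given the SD of 0.98 of the Gata3 values themselves. Where this probe lies relative to the deleted part of Gata3 is not given in the sources used here, so its value does not settle the sign of the ratios.

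The comparison of het and null glands over the whole array asked which transcripts depend on Gata3. Csn1s1, which encodes the milk protein alpha-S1 casein, ranked first among named genes by the smaller of its ratios on the arrays, with a mean of 1.88 ± 0.24 (SD, n = 2; limma adjusted p = 0.0512). On the positive side it was followed by Fam13c at 1.81 ± 0.28 (SD, n = 2). Next came Tmem209, with ratios of 2.40 on array 1 and 1.59 on array 2, and then Cpne3, a calcium-dependent phospholipid-binding protein, at 1.87 ± 0.52 (SD, n = 2). The other positive genes were Sult1c1, a sulfotransferase (1.56), Bex2 (1.55), Pnpla8, a phospholipase (1.83), Actc1, the cardiac alpha-actin (1.78), Ccni (1.67), F8a (1.49), Lrrc41 (1.49) and Mcmdc2 (1.42). On the negative side, Hmgn1, a nucleosome-binding protein, had a mean ratio of -1.54 ± 0.18, Zbtb7c -1.59 ± 0.26 and Tfap2d, an AP-2 family transcription factor, -1.66 ± 0.41 (SD, n = 2 each). Mtf2, a Polycomb-associated protein, stood at -1.60, and Id3, an inhibitor of basic helix-loop-helix transcription factors, at -1.38.

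The remaining negative genes were Ephb6, an Eph receptor (-1.32), Atg5, needed to form autophagosomes (-1.42), Phlda2, an imprinted gene (-1.48), Zfand2b (-1.36), the ribosomal protein genes Rps29 (-1.48) and Rpl41 (-1.27), and Edn3, an endothelin (-1.31). None of these 24 genes passed the test over features, and the adjusted p of each was 0.0512. Of the 24 genes, 12 had further features, 15 in all, and the gene values above are those of a single feature each. A second Csn1s1 feature gave -0.52 on array 1 and 0.87 on array 2. The other features of positive genes had means of 0.64 for Fam13c, 0.22 for Tmem209, 0.82 and 0.05 for Cpne3, 0.17 and -0.25 for Pnpla8, 0.72 for Actc1, 0.11 for Ccni and 1.06 for F8a. Those of negative genes had means of 0.29 for Hmgn1, -0.15 for Mtf2, -0.03 for Atg5, and -0.23 and -0.67 for Zfand2b.

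By limma's moderated test against 0, 0 features with a positive ratio and 0 with a negative ratio passed an adjusted p of 0.05. The lowest adjusted p was 0.0512 and was shared by 1477 features. At an unadjusted p under 0.05 there were 6038 positive and 2521 negative features, 22.0% of all, where chance alone would give 1949 features. The count of 0 lay at the edge of the threshold. Subtracting each array's median gave 2453 positive and 271 negative features, and averaging the features of a gene before the test gave 1096 positive and 148 negative genes. The lowest adjusted p at the gene level was 0.0336, so the single genes said below to pass lay between 0.0336 and the threshold. They passed in that gene-level fit and not over features. In the same gene-level fit 19 of the 24 genes named above passed, among them all 12 with 1 feature, such as Sult1c1, Ephb6 and Tfap2d (limma adjusted p = 0.0336 each). Csn1s1 (adjusted p = 0.0545), Pnpla8 (0.131), Hmgn1 (0.0861), Atg5 (0.0550) and Zfand2b (0.0704) did not. All 24 were picked from these same data as the most extreme, and the genes with 1 feature have the same values in both fits. Passing at the gene level is therefore no further support for them.

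Features 2-fold or more from 0 on both arrays numbered 835 with positive and 99 with negative ratios. Shuffling the features of array 2 in 1000 draws gave a mean of 104.5 positive features (73 to 136) and 10.8 negative features (1 to 24). Across all features the ratios of the arrays had a Pearson r of 0.587 and a Spearman rho of 0.489, and 65.5% had the same sign. These are correlations across features, which are not independent replicates. With both arrays in one dye orientation, a bias of a probe towards one dye would be shared by both arrays in the same way as a difference between genotypes. Olfactory receptor genes, 844 on the array, had positive medians of 0.51 on array 1 and 0.42 on array 2.

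**Figure D1:**
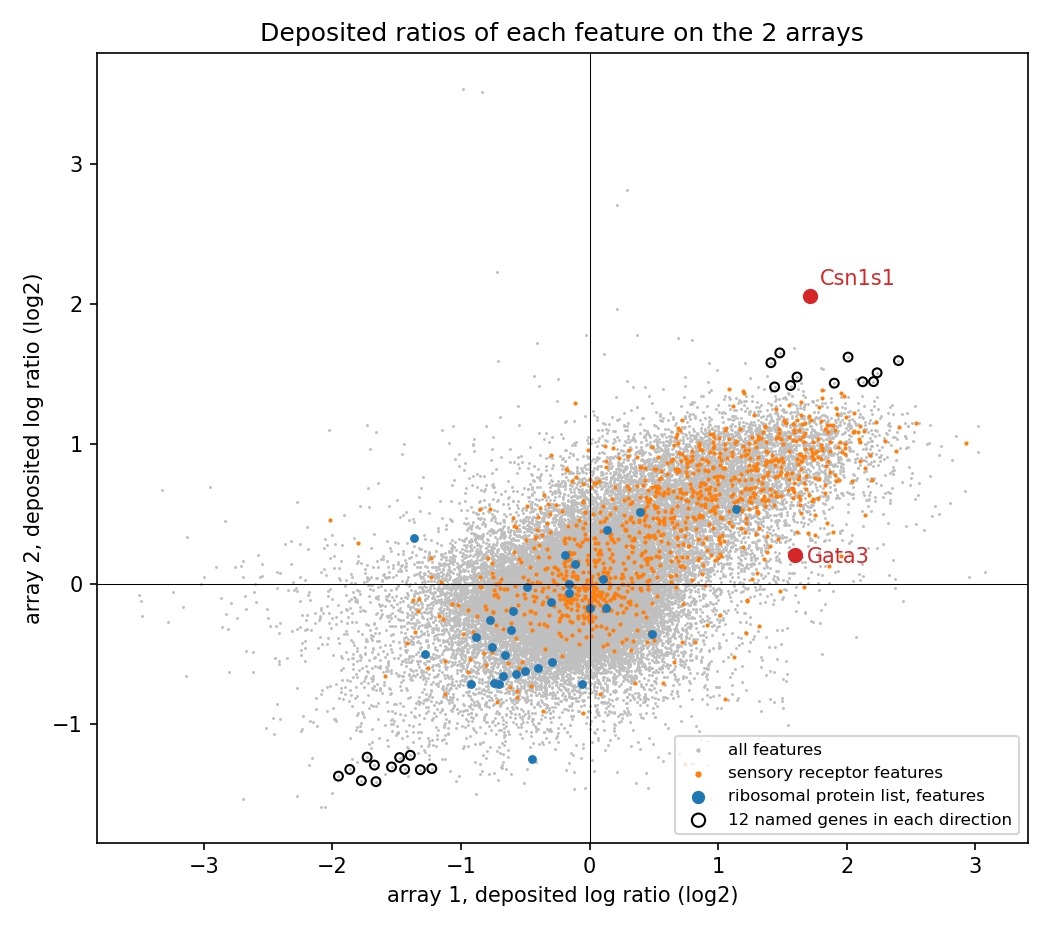
Deposited log2 ratio of each of the 38976 features on array 1 (horizontal) against array 2 (vertical), with sensory receptor features, the features of the ribosomal protein list, and the 12 named genes of each direction marked. Csn1s1 lies at 1.71 and 2.06, and Gata3 at 1.60 and 0.21.

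For 13 genes with 20 or more features each, called repeated genes below, the spread of the features within an array was measured. Whether these features are copies of 1 probe or different probes is not given in the sources used here. The spread may therefore include differences between probes. Ywhaz, a 14-3-3 protein, had a mean ratio of 0.73 ± 0.65 on array 1 and 0.70 ± 0.45 on array 2 (SD over 77 features). B2m, the light chain of class I histocompatibility molecules, stood at -1.23 ± 1.15 on array 1 and -0.14 ± 0.32 on array 2 (SD over 75 features). Gapdh, a glycolytic enzyme, was at -1.16 ± 0.57 and -0.43 ± 0.32 over 30 features. Hprt, by contrast, was at 0.01 ± 0.49 and 0.10 ± 0.26 over 78 features. The median SD within a gene was 0.49 on array 1 and 0.29 on array 2.

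Gene lists for the cell types and processes of the gland were compared with all other genes. The gene-level test passed 1244 of all 15056 genes, so a few passing members say little about a list. The same holds for members adjusted over a list alone, which 13 of the 23 lists had. That adjustment does not allow for the number of lists, and 3584 of all genes had an unadjusted p under 0.05 (limma). Genes of cytosolic ribosomal proteins had negative ratios as a group, with 19 of 23 measured genes negative on both arrays, 1 positive on both and 3 of opposite sign. Their median was -0.46 on array 1 and -0.37 on array 2. The most negative were Rpl32 (-0.89), Rpl30 (-0.82), Rpl13 (-0.73) and Rpl8 (-0.71), as means of both arrays. Rpl13a, a repeated gene outside the list, had means of -0.08 on array 1 and -0.16 on array 2 over 22 features. With 0 arrays dye-exchanged, a dye or labelling effect on these genes cannot be told apart from a genotype difference. The list passed limma's camera test with its preset correlation (adjusted p = 7.08e-05 over 23 lists). With the correlation preset, that test compares member genes with other genes. Its p therefore does not measure the spread between arrays or animals. The list did not pass with an estimated correlation, here 0.051 (adjusted p = 0.819). Nor did it pass with fry, which asks whether the genes of a list move one way (adjusted p = 0.445). Both of these tests rest on 1 residual degree of freedom, so a list could hardly pass them, and 0 lists passed either. Failing them therefore neither bears out nor refutes the shift. Rpl30 passed the gene-level limma test over all genes, and 5 members passed when adjusted over the list alone.

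The other 22 lists did not pass, with adjusted p from 0.0686 to 0.986 (limma camera). Genes of fibroblasts and the interstitial matrix came next (adjusted p = 0.0686), with 11 of 19 negative on both arrays. Col1a1, a chain of collagen I, had ratios of -1.78 and -0.07, Fn1 -0.45 and -0.51, Dcn -0.66 and -0.20, and Mmp2 -0.47 and -0.21. White adipocyte genes had medians of -0.37 on array 1 and 0.01 on array 2 (adjusted p = 0.176). In that list Adipoq, the adipokine adiponectin, stood at -1.74 and -0.41, Car3 at -1.77 and -0.15, and Cd36 at -1.22 and -0.28, while Thrsp had a mean of -0.71. No member of the fibroblast or white adipocyte list passed over all genes or adjusted over the list alone.

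The luminal hormone-sensing list, which holds genes of estrogen receptor-positive cells, had medians of -0.28 and -0.07 (adjusted p = 0.141), with 6 of 15 genes negative and 2 positive on both arrays. Wnt4 stood at -1.37 and -0.38, Tph1 at -1.03 and -0.19, Esr1, the estrogen receptor gene, at 0.73 and 0.48, and Cited1 at -0.57 and -0.19. No member passed over all genes or adjusted over the list alone. Foxa1, the pioneer factor of luminal cells, gave -1.30 and 0.15, opposite signs on the arrays. For luminal keratins, junctions and surface proteins the list's adjusted p was 0.371, and members went both ways. Aldh1a3, an aldehyde dehydrogenase (1.29), and Cd24a, a cell surface glycoprotein (1.07), passed the gene-level limma test with positive ratios, both over all genes and adjusted over the list alone. The keratins Krt8 (-0.62) and Krt18 (-0.62) did not pass.

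Milk and alveolar genes had an adjusted p of 0.514 as a list, with 10 of 25 genes negative and 7 positive on both arrays. Milk protein genes went both ways. Csn3, which encodes kappa-casein, had a ratio of 0.93 ± 0.18 (SD, n = 2) and passed the gene-level limma test, as did Plin2, a lipid droplet coat protein, at -1.15 ± 0.57 (SD, n = 2). Csn1s1 averaged over its features stood at 1.03, and Atp2b2 at -0.60, and neither passed over all genes. Csn2 had ratios of -0.42 on array 1 and -0.25 on array 2, and Lalba -0.34 and -0.29, and neither passed. In this list 3 members passed when adjusted over the list alone. Basal myoepithelial genes (adjusted p = 0.986) included Krt5 at -0.97, which passed over all genes, and Krt14 at 0.81, Itga6 at 0.45 and Krt17 at -0.29, which did not. Adjusted over the basal list alone, 0 members passed. Basement membrane genes and receptors (adjusted p = 0.640) held Itgb1 at -0.65, Itga3 at 0.55 and Col7a1 at -0.42, besides Itga6, with 0 members past the test on either count.

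Among immune lists, macrophage and myeloid genes had medians of -0.36 and -0.11 (adjusted p = 0.141). Ctss, cathepsin S, passed over all genes at 1.45, against the list's median, while Adgre1 (0.90), Laptm5 (-0.71) and Itgam (-0.65) did not, and 5 members passed when adjusted over the list alone. The interferon list had an adjusted p of 0.141 and 0 members past the test on either count. It contained Rsad2 at 0.78, Irf7 at -0.77, Stat2 at -0.49 and Ifit2 at -0.48. T cell and lymph node genes (adjusted p = 0.451) included Cd3g, which passed over all genes at 0.89, with Glycam1 at -0.58, Cd247 at -0.46 and Coro1a at -0.35 not past it. In the B cell list (adjusted p = 0.656) H2-Aa, a class II chain, passed over all genes at 1.24, and Pou2af1 (0.71), Cr2 (-0.55) and Cd79b (-0.37) did not. Adjusted over each list alone, 1 T cell gene and 1 B cell gene passed.

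Metabolic and proliferative lists also held members of both signs. Oxidative phosphorylation genes had medians of -0.17 and -0.13 (adjusted p = 0.141), with Atp5b at -0.94, Ndufs1 at 0.66, Cycs at 0.63 and Cox6a1 at -0.61, and 0 members past the test on either count. In fatty acid and sterol synthesis (adjusted p = 0.986) the desaturase gene Scd2 (1.17) and Srebf1, a lipogenic transcription factor (1.01), passed over all genes. Scd1 (-1.19) and Slc25a1 (-1.01) did not, and 2 members passed when adjusted over the list alone. Among cell cycle genes (adjusted p = 0.981), Pcna, the replication clamp (1.35), and Ube2c, a ubiquitin-conjugating enzyme of mitosis (1.25), passed over all genes. Ccna2 (0.76) and Aurkb (0.76) did not, and 5 members passed when adjusted over the list alone. For brown adipocyte genes (adjusted p = 0.234), Otop1 passed at 1.21 on both counts, and Cox7a1 (0.67), Fabp3 (0.55) and Ppargc1a (0.51) did not pass over all genes.

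In the cell death and p53 list (adjusted p = 0.371) Gadd45a, a growth arrest and DNA damage gene, passed on both counts at -1.35, and Apaf1 (0.49), Casp9 (-0.42) and Bcl2l11 (0.39) did not pass over all genes. Involution and acute phase genes (adjusted p = 0.371) included Osmr, the oncostatin M receptor (0.83), and Ctsl, cathepsin L (0.81), past the test over all genes, and Bcl3 (-0.88) and Ctsd (-0.64), which were not. In the unfolded protein and heat shock list (adjusted p = 0.981) the chaperones Canx (1.11) and Hspa8 (-1.02) and the stress gene Herpud1 (0.91) passed over all genes, and Pdia3 (-0.68) did not. Adjusted over each list alone, 5 genes of involution and 5 of the unfolded protein list passed.

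The lists of other tissues in the gland gave adjusted p of 0.268 for skeletal muscle, 0.986 for skin, 0.640 for erythroid and 0.986 for endothelial genes. Lor, which encodes the cornified envelope protein loricrin, passed on both counts at 1.01, and Calml3 (-1.10) and Lgals7 (0.10) did not pass over all genes. Muscle genes Tnnc2 (-0.74), Casq1 (-0.71), Pvalb (0.62) and Actn3 (-0.44), erythroid genes Car1 (0.58), Slc4a1 (-0.43), Car2 (0.29) and Epb42 (0.25), and endothelial genes Kdr (0.61), Cldn5 (-0.56), Tek (0.50) and Sox17 (0.38) did not pass. For the cell cycle, fatty acid, B cell, endothelial and unfolded protein lists, the median, the mean and the direction of the test did not share one sign.

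**Figure D2:**
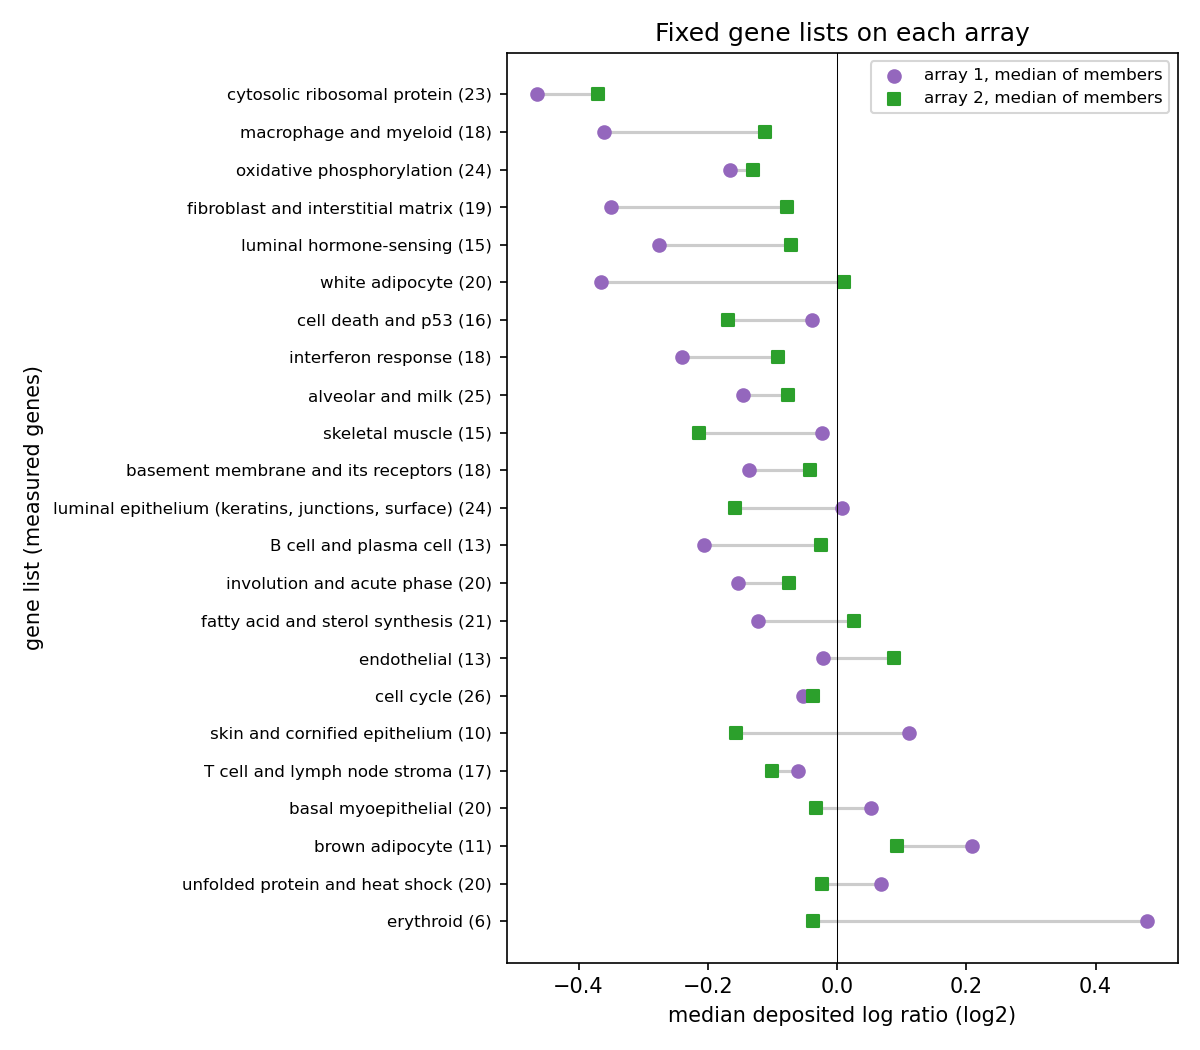
Median deposited log2 ratio of the measured genes of each of the 23 lists (horizontal) on array 1 (circles) and array 2 (squares), with the number of measured genes beside each name. Cytosolic ribosomal protein genes lie lowest, at -0.46 and -0.37.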

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

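Leaving out sensory receptor genes and scaling 48 equal runs of features alike were chosen after seeing the data. The count of 0 features past limma's test changed most. It became 2724 (2453 positive, 271 negative) with each array's median subtracted, 5014 (4221 and 793) with equal median absolute deviation, 5121 (4139 and 982) after quantile normalization, 3219 (2828 and 391) with the runs scaled alike, 1244 for genes in place of features and 4929 at an adjusted p of 0.1. Dropping features whose arrays differed by more than 1 gave 7452, a filter that by construction removes the features with the largest spread. The lowest adjusted p of 0.0512 lay just above the threshold. The count stayed at 0 with a robust prior and without sensory receptor genes. Turning the sign and the stricter treat could not raise a count of 0, so they tested nothing. The same holds for allowing features with a value on 1 array, which added none. A single array leaves no residual degrees of freedom, so the test was not run without either array.

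The 934 features 2-fold from 0 on both arrays became 4619 at 1.5-fold, 11 at a log2 minimum of 1.5, 1519 with equal median absolute deviation and 323 as genes, and between 1407 and 5191 on a single array. They were 1068 with medians subtracted and 850 without sensory receptor genes. Sensory receptor features made up 84 of the 541 named positive ones (15.5%) and 0 of the 56 named negative ones. Among all named features their share was 4.57%. The correlation of 0.587 was 0.573 without the 1% largest ratios and 0.576 without sensory receptor genes. The Gata3 mean of 0.90 was 0.92 with medians subtracted and 0.81 with equal median absolute deviation, and 0.21 to 1.60 on single arrays. With 2 arrays, each necessarily lies within 1 SD of the mean, so leaving one out says nothing of stability for Gata3 or the 24 named genes.

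On simulated data camera itself called 1 of 19 unshifted lists. The count of 1 list past camera fell to 0 with an estimated correlation and 0 with fry. It was 2 with camera on ranks (fibroblast matrix added), 2 against random lists (macrophage added; on simulated data random lists called 2 of 19 unshifted lists) and 3 with features in place of genes (fibroblast matrix and involution added). On single arrays, between 3 and 6 lists had medians outside percentiles 2.5 to 97.5 of random lists of equal size, a description and not a test. The ribosomal list's adjusted p ranged from 2.84e-05 to 0.819 over its alternatives, and it was lost with an estimated correlation (0.819) and fry (0.445). Those 2 tests rest on the 1 residual degree of freedom left by 2 arrays, so failing them says little about the list. Besides, the ribosomal list's estimated correlation was 0.051 against the preset 0.01, and a larger correlation raises camera's p. How much of the change each accounts for was not tested. The interferon list's estimated correlation of -0.046 was below the preset 0.01, yet its unadjusted camera p rose from 0.024 to 0.247. Apart from the filter, which acts by construction, and the few degrees of freedom of these tests, the cause of the changes was not tested.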

Other observations

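The gene families below, 15 by symbol, were chosen after the values were seen. Olfactory receptor genes had positive ratios on both arrays for 546 of 844 genes, with medians of 0.51 and 0.42. Vomeronasal receptors had medians of 0.31 and 0.32 over 132 genes, and type 2 taste receptors 0.55 and 0.28 over 28 genes. Histone genes went the other way, with 50 of 69 negative on both arrays and medians of -0.43 and -0.41. Mitochondrial ribosomal protein genes, 74 in all, had medians of -0.07 and -0.16. The 80 genes matching the symbol pattern of cytosolic ribosomal proteins lay further from 0, at -0.46 and -0.40. That pattern would also take in Rps6k kinase genes, which do not encode ribosomal proteins. Zinc finger Zfp genes had a median of 0.04 on array 1 over 230 genes, and on array 2 their median changed sign between scalings (-0.01 to 0.03). Keratin-associated protein genes had medians of 0.24 and 0.19 over 28 genes, beta-defensins 0.02 and 0.09 over 25, and the prolactin family 0.02 and 0.41 over 22. Keratins stood at -0.07 and -0.24 and collagens at -0.14 and -0.03, each over 36 genes, complex I subunits at -0.04 and -0.15 over 28 genes, and cystatin Cst genes at -0.22 and -0.16 over 7. The trace amine receptor family had 1 gene, at 1.18 and 0.79.

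The arrays differed in several tissue lists, as values with no test of the difference. White adipocyte genes stood at percentile 0.05 of random lists on array 1 and 61.1 on array 2. Fibroblast matrix genes stood at 0.035 and 22.5, and macrophage genes at 0.13 and 11.98. Ribosomal protein genes lay below all random lists, at percentile 0, on both arrays. Luminal epithelial genes were at percentile 47.6 on array 1 and 2.11 on array 2. Fabp4, a fatty acid-binding protein of adipocytes, had ratios of opposite sign, -0.904 and 0.997.

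Of the tests below, those of repeated genes and of neural transcription factors were chosen after some such values had been seen. The receptor medians and the growth of spread over all features were also known beforehand. The first pattern is that the arrays agree across features. If this came wholly from transcripts that differ between genotypes, genes of sensory receptors, presumed little expressed in the gland, should agree less than others. Their r was 0.711 (95% 0.676 to 0.745, 1005 genes), above that of 14051 other named genes by 0.125 (0.0865 to 0.163), which argues against genotype as the whole cause as far as that presumption holds. A probe effect of dye or labelling common to both arrays predicts such an r and may account for part of the agreement. A part due to genotype stays open, since 0 arrays had the dyes exchanged.

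The second pattern is the positive ratio of sensory receptor genes. A low transcript level in the gland and the base composition of the probes were considered, with a list of neural transcription factors as the comparison. The 67 measured had medians of -0.039 (95% -0.14 to 0.07) on array 1 and -0.13 (-0.24 to -0.02) on array 2, and receptor genes lay above them by 0.54 (0.41 to 0.67) and 0.52 (0.40 to 0.65). The list was prompted by neural transcription factors seen among the most negative features, so these values decide neither explanation. Probe sequences and signal were not used here, a genotype effect on receptor transcripts was not tested, and all of these stay open.

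The third pattern is a spread that grew along the feature order, from an SD of 0.49 in the first of 48 runs to 0.78 in the last on array 1, and from 0.31 to 0.51 on array 2. Among sensory receptor features the SD in the last 25% of the order was 1.38 times that in the first 25% on array 1 (95% 1.23 to 1.55) and 1.35 times on array 2 (1.21 to 1.497), so place in the order may play a part. A different gene content along the order was tested with the repeated genes, whose SD in the last 50% of the order over that in the first 50% was 1.36 (1.12 to 1.64) on array 1 and 0.977 (0.813 to 1.17) on array 2. The draws for these intervals took features as units, and the 654 features came from 13 genes, so the intervals may be too narrow. The arrays gave different answers, so gene content as the whole cause could be neither excluded nor borne out. No biological explanation was tested for this pattern.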
